A study of Niallia circulans and Nakaseomyces glabratus and Aspergillus flavus with 18 samples.

How the data were processed

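RNA was sequenced from 3 microorganisms grown with or without the essential oil of Neolamarckia cadamba, a tropical tree. Per the labels' protocols, cultures in logarithmic growth were given the oil at its MIC (the minimum inhibitory concentration) or were left without it, and were cultured for another 4 h, the bacterium at 37 °C and the fungi at 28 °C. The concentration behind the MIC is not given in the sources used here. Each species has 3 control and 3 oil libraries, 18 in all. The labels do not say whether replicates came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical. No sequencing batch or date is given in the sources used here.

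Per the labels' protocols, RNA was extracted with TRIzol, mRNA was fragmented, and cDNA was made with SuperScript II and random priming. No step that marks the strand is described. Trimmomatic 0.38 and FastQC 0.11.5 are named in the submitters' processing notes. The aligner, counter, genome build and annotation are not given in the sources used here. Reads of paralogs and overlapping or antisense genes therefore cannot be assigned with certainty.

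The authors deposited FPKM values (fragments per kilobase, scaled to library size) for Bacillus circulans, whose organism label is Niallia circulans, with columns that summed to between 2048730 and 2509710. The authors deposited TPM values (transcript abundance scaled to a fixed library total) for Candida glabrata and Aspergillus flavus, and each of those columns summed to 1000000. The B. circulans table held 5198 rows, of which 4949 carried a locus tag (4946 protein-coding and 3 ncRNA) and 911 of these a gene symbol, with a product description beside them. The C. glabrata values covered 5212 locus tags and those of A. flavus 12009, and these tables do not pair the tags with gene names. No genome was used here. The fungal genes are therefore given as counts, with at most 2 rising and 2 falling tags per species, and the fungal gene lists and the comparison of lists between species were not run.

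The remaining rows were assembled features without a gene name: 249 in B. circulans (192 of them named as antisense), 69 in C. glabrata and 901 in A. flavus. They were left out of the tests. In B. circulans they held between 74.7% and 83.1% of the reads of a library, and 2 of them alone held between 56.4% and 67.2%. In C. glabrata they held between 0.198% and 0.329% of the reads, and in A. flavus between 1.31% and 2.77%.

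Within each row, the values of the 6 libraries stood in ratios of whole numbers after 1 factor per library, at a relative tolerance of 1e-12. The smallest whole numbers with these ratios were taken as reads. They were found for 100% of the rows above 0 in B. circulans and A. flavus and for 99.981% in C. glabrata, where the row without them was the most abundant one. A row whose true reads share a common factor would be given too few, so the reads are lower limits. They served to describe depth, for thinning and for 1 alternative test. Replicate libraries differed by more than sampling noise, with chi-square values per degree of freedom between 6.07 and 219, so each was counted as its own sample.

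The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), fitted to each species alone with a term for the oil, an intensity trend in the variance prior and no block. Genes with a mean of at least 1 over the 6 libraries were tested, 2667 in B. circulans, 5155 in C. glabrata and 8472 in A. flavus. P-values were two-sided and Benjamini-Hochberg adjusted over the genes tested, with a threshold of 0.05. Changes are on the log2(value + 1) scale, which understates the change of low genes. The 17 B. circulans gene lists were defined by symbol and product name before the data were examined, as were the tests and the other settings listed below, except where stated. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 17 lists, each with at least 5 tested genes. Some product patterns took in genes outside a list's theme, which are named where they matter. Group values of a single measure were compared by exact two-sided permutation tests, which cannot give less than p = 0.1 with 3 libraries against 3.

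Named genes followed a rule fixed before the data were examined. It takes the 6 largest rises and 6 largest falls past the threshold with a mean of at least 10 in the higher group, no overlap between groups and an informative name, and from each list the 2 largest changes past the threshold. Where no gene passes it takes the 6 named genes with the smallest p, and from each list the gene of the highest mean, given as a value. Genes outside the rule are marked as chosen after their values were seen.

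Alternatives were other pseudocounts (0.1 and 5), no filter or a mean of at least 10, median centring, quantile normalization, limma without the trend or with robust priors, a replicate block, a 2-fold minimum, and each library left out in turn. For the lists, camera with an estimated correlation and fry were also run. A planned count test on the recovered reads was not run because the units are FPKM and TPM. limma-voom on those reads took its place, chosen after seeing the data, as were the inclusion of unnamed features, the block combined with median centring, and for B. circulans a scaling to the reads of protein-coding genes. The limma-voom fit kept the library scaling of the deposited values, so it does not check that scaling.

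The gene test was tested on simulated reads with the means, depths and typical dispersion of each species, with 200 genes of enough depth changed, 100 by 2-fold and 100 by 4-fold, in 5 simulations. For C. glabrata it recovered 99.8% of the 2-fold and 100% of the 4-fold changes, for A. flavus 78.4% and 96.4%, and for B. circulans 6.4% and 60.2%. False calls were 5.03%, 5.19% and 6.87% of the calls on average. In the simulated reads genes varied independently. In the real B. circulans libraries the correlations estimated within lists ran from 0.173 for purine and pyrimidine synthesis to 0.822 for heat shock. The list test called the amino acid synthesis list, when raised 2-fold, in 5 of 5 B. circulans simulations. No other list was raised and the simulated genes were independent, so this does not give the power for the real lists.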

Results

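The series asked how transcription in a bacterium and 2 fungi responds to Neolamarckia cadamba essential oil. Bacillus circulans is a spore-forming bacterium, Candida glabrata a yeast and Aspergillus flavus a filamentous fungus, each measured in 3 control libraries and 3 libraries taken 4 h after the oil was added. The recovered reads in locus tags numbered 27383709 to 34254069 in the C. glabrata control libraries and 13809210 to 16926895 in its oil libraries. These totals leave out its most abundant gene, whose reads were not recovered. That gene held 4.38% of the TPM of locus tags in controls and 12% after the oil, so the oil totals are understated more. In A. flavus they numbered 5901145 to 6830358 in the control libraries and 3024377 to 4123571 in the oil libraries. In B. circulans they numbered 875578 to 1493126, so that the median tested gene had between 14 and 30 reads in a library. The oil libraries of both fungi were thus shallower than their controls (exact permutation p = 0.1 for each, the smallest that 3 against 3 allows).

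**Figure D1:**
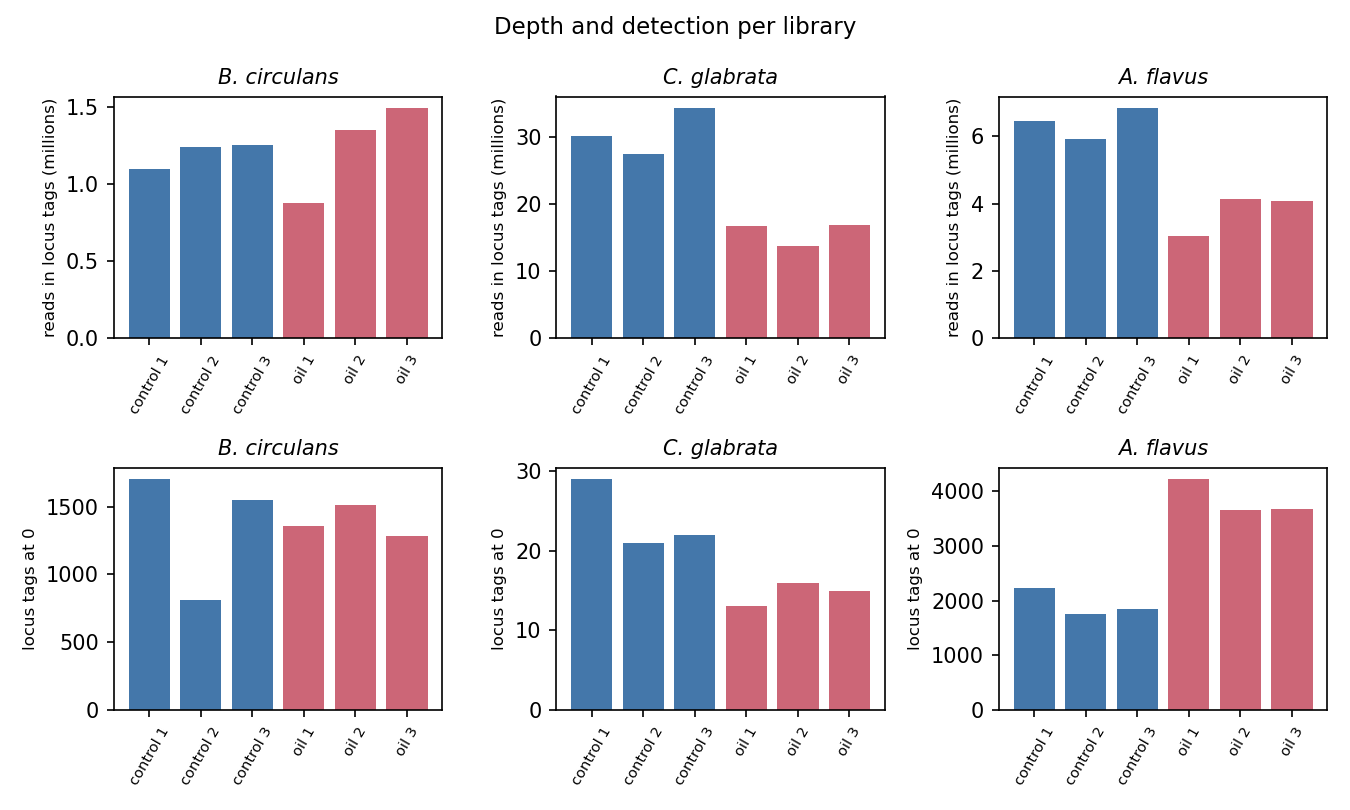
Recovered reads in locus tags (top row, axis in units of 1000000) and locus tags listed at 0 (bottom row) in each library of the 3 species, with control libraries in blue and oil libraries in red. Oil libraries of C. glabrata and A. flavus had fewer reads than their controls, and locus tags at 0 averaged 1942 in A. flavus controls and 3852 in its oil libraries.

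In B. circulans no gene passed the threshold after the oil. Among 2667 tested genes, limma gave 0 higher and 0 lower genes at adjusted p under 0.05. With the same library scaling, limma-voom on the recovered reads also gave 0 and 0. At an unadjusted p under 0.05, 76 genes were higher and 47 lower by limma, 4.61% of the genes tested, and 80 were higher and 37 lower by limma-voom. Chance alone gives 5% at that threshold. The number at an unadjusted p under 0.05 depended on the scaling: limma gave 277 with median centring, 297 with quantile normalization and 420 with scaling to the reads of protein-coding genes. Of the 6 genes with an informative name and the smallest p values, 3 code for subunits or binding proteins of transporters. Hypothetical proteins were passed over, among them FOC77_RS13835, chosen after its values were seen, with 43.7 ± 5.38 and 12.5 ± 6.91 FPKM (SD, n = 3), whose limma adjusted p of 0.232 was the second smallest and became 0.0307 with median centring. FOC77_RS25265, subunit IIB of a PTS sugar transporter (the phosphotransferase system, which takes up sugars while phosphorylating them), had 2.32 ± 1.41 FPKM in controls and 17.4 ± 13.5 after the oil (SD, n = 3), a log2 change of 2.34 with a standard error of 0.50 and a limma adjusted p of 0.0572. It had only 2, 7 and 8 reads in the controls. With 1 library left out its limma adjusted p ran from 0.00561 without control replicate 2 to 0.638 without control replicate 1, where the log2 change was 1.93, and it was also under the threshold without control replicate 3 (0.0268). Over all alternatives it ran from 0.00338 with robust priors to 0.638, and it was 0.0379 with the replicate block and 0.0336 with unnamed features included. The neighbouring tag celB (FOC77_RS25260), a PTS cellobiose transporter subunit IIC, had 4.6 ± 3.78 and 16.1 ± 8.2 FPKM (SD, n = 3), with a limma adjusted p of 0.363 that became 0.0454 without control replicate 2. FOC77_RS23665, an extracellular solute-binding protein, had 16.4 ± 9.8 and 57.5 ± 26.5 FPKM (SD, n = 3), with a limma adjusted p of 0.333 that became 0.0179 among genes with a mean of at least 10 and 0.0414 without control replicate 2. Both celB and FOC77_RS23665 had a limma adjusted p near 1 without control replicate 1. FOC77_RS00830, a G5 and 3D domain-containing protein, had 31.6 ± 6.55 and 101 ± 34.3 FPKM (SD, n = 3), with a limma adjusted p of 0.363 that became 0.0307 with median centring. The other two genes of this rank also rested on few reads. rpoZ, the omega subunit of RNA polymerase, was listed at 0 in all 3 oil libraries and had 9, 1 and 2 reads in the controls. sspO, a small acid-soluble spore protein, had 3, 2 and 3 reads in the controls and 0, 0 and 2 after the oil.

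**Figure D2:**
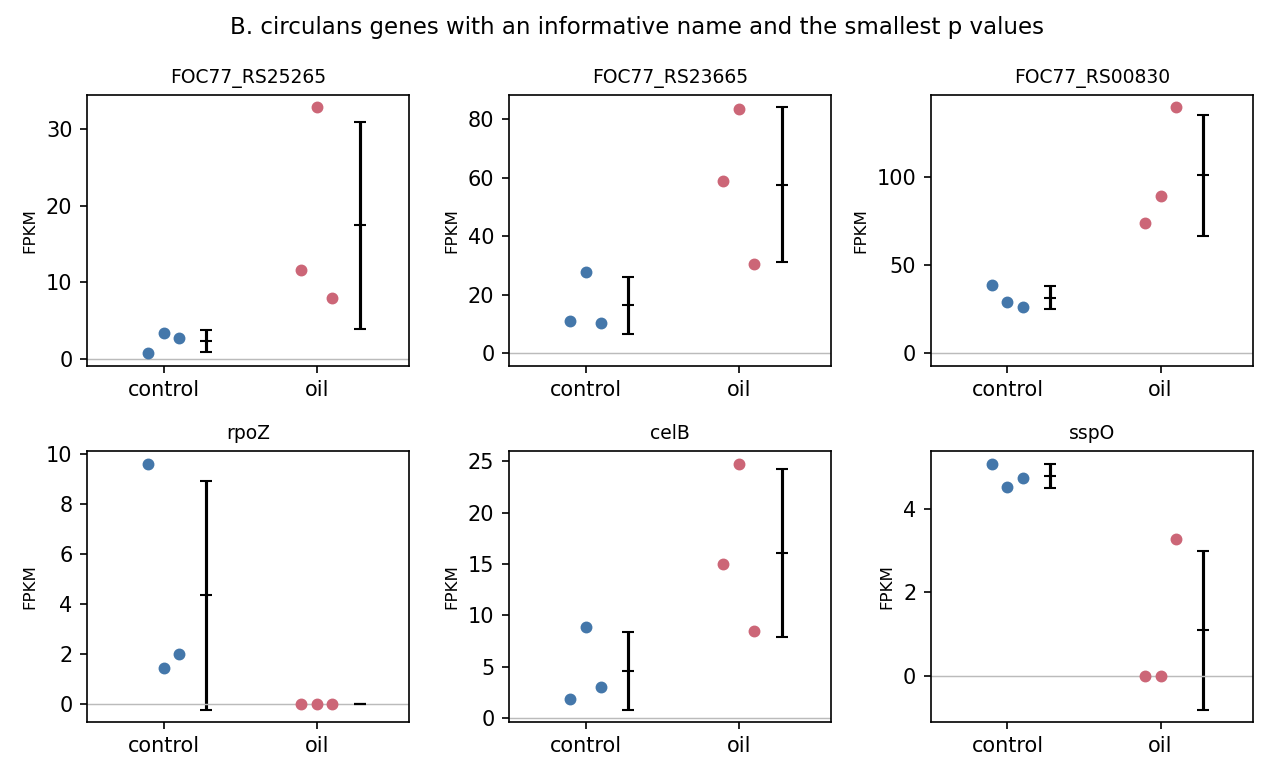
FPKM in each library of the 6 B. circulans genes with the smallest p values among those with an informative name (points, control in blue and oil in red), with the mean and SD of 3 libraries in black. FOC77_RS25265 averaged 2.32 FPKM in controls and 17.4 after the oil, and rpoZ was listed at 0 in the 3 oil libraries.

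None of the 17 B. circulans gene lists passed the threshold, and none of their members passed it over all genes tested. The prophage list had a median log2 change of -0.51 over 12 tested genes, with 9 of them below 0 (camera adjusted p = 0.0512, and adjusted p = 0.99 with an estimated correlation). Its most abundant member, a phage holin family protein (FOC77_RS20735), had 227 ± 50.6 FPKM in controls and 212 ± 49.3 after the oil (SD, n = 3, log2 change -0.11). Chosen after their values were seen, the largest falls were those of a PBSX family phage terminase large subunit (FOC77_RS13820, log2 change -1.07) and a terminase small subunit (-0.80), which belong to DNA packaging. The 3 members above 0 were another holin family protein (0.81), a CidA/LrgA family holin-like protein (0.26) and a betaine, proline and choline transporter subunit (0.40) that matched only by the letters of its name, also chosen after their values were seen. Flagellum and chemotaxis had a median of -0.18 over 53 genes, with 35 below 0 (camera adjusted p = 0.0512, and adjusted p = 0.99 with an estimated correlation). Flagellin, the filament protein and the list's most abundant member, had 28783 ± 14247 FPKM in controls and 15682 ± 5843 after the oil (SD, n = 3). Its log2 change of -0.83 became 0 with quantile normalization, which gives equal values to genes of equal rank. 1 member, flgM, chosen after its value was seen, had a log2 change of 1.54 (limma adjusted p = 0.894). It was listed at 0 in controls and at 2.87 ± 3.14 FPKM after the oil (SD, n = 3), so that change rests on values near 0. With median centring both lists passed, at camera adjusted p = 0.00927 for prophage and 0.00856 for flagellum and chemotaxis. With an estimated correlation their adjusted p after centring were 0.567 and 0.666.

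The lists of envelope stress and general stress had medians above 0, and neither passed. Envelope stress had a median log2 change of 0.27 over 16 genes, 13 of them above 0 (camera adjusted p = 0.0767). With median centring its camera adjusted p was 0.0415, and adjusted p = 0.567 with an estimated correlation. Its most abundant member, an Asp23/Gls24 family protein, had 110 ± 31.3 FPKM in controls and 164 ± 57.3 after the oil (SD, n = 3). It also held genes outside the theme. Among them were flgM, the anti-sigma factor of flagellar genes, the sporulation regulators spoIIAA and spoIIAB, and an anti-sigma-F factor Fin family protein. The anti-sigma B factor rsbW, a gene of the general stress list, was a member as well, so the lists overlap. General stress had a median of 0.13 over 7 genes, 4 above 0 and 3 below (camera adjusted p = 0.0767). Its most abundant member, a general stress protein (FOC77_RS18545), had 63.8 ± 16.6 FPKM in controls and 62 ± 25.3 after the oil (SD, n = 3, log2 change -0.09). The other genes of this list named here were chosen after their values were seen. sigB, the sigma factor of general stress, had a log2 change of -0.25 and rsbW, its anti-sigma factor, one of -0.12. When adjusted over the list alone 2 genes passed, both with values near 0 in the controls: prli42, a stressosome-associated protein listed at 0 in controls and at 2.81 ± 0.906 FPKM after the oil, and a general stress protein (FOC77_RS24405) with 1.28 ± 1.21 and 5.87 ± 5.51 FPKM (SD, n = 3). No other list had a gene that passed when adjusted over the list alone. With median centring 3 lists had such genes. In general stress 2 passed, prli42 and another general stress protein (FOC77_RS19660, log2 change 0.80). In prophage 2 passed, the terminase large subunit (-1.10) and small subunit (-0.83), and in the heat shock list 1 passed, the chaperone gene dnaJ (-1.06, chosen after its value was seen). Estimated correlations gave adjusted p = 0.99 for both stress lists and for every other list.

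Genes of the basic cell machinery showed medians near 0, and their tests did not pass. These medians depended on oil replicate 1, and the median over all tested genes also moved with other libraries. With 1 library left out, that overall median ran from -0.16 without oil replicate 3 to 0.21 without oil replicate 1. It was 0.19 without control replicate 2. Without oil replicate 1 the list medians were 0.23 for ribosomal proteins, 0.22 for heat shock and 0.26 for oxidative defence. For respiration, glycolysis and the TCA cycle they were 0.17, 0.33 and 0.15, beside 0.21 over all tested genes. The 55 ribosomal protein genes had a median of -0.10 and a mean of 0.03, opposite in sign (camera adjusted p = 0.741), with rpsU at 1069 ± 173 FPKM in controls and 937 ± 453 after the oil (SD, n = 3). Among 18 heat shock chaperones and proteases the median was -0.08 (camera adjusted p = 0.467), and groL, the chaperonin GroEL, had 3024 ± 1158 and 2592 ± 815 FPKM (SD, n = 3). The camera adjusted p was 0.968 for oxidative defence, where spxA had 378 ± 69.2 and 461 ± 157 FPKM (SD, n = 3). It was 0.565 for respiration and ATP synthase, where atpD, the beta subunit of ATP synthase, had 1381 ± 32.6 and 1540 ± 599 FPKM (SD, n = 3). Glycolysis had a median of 0.01 and gap, glyceraldehyde-3-phosphate dehydrogenase, had 4512 ± 576 and 4278 ± 1109 FPKM (SD, n = 3), with a camera adjusted p of 0.741. The TCA cycle list had a median of -0.16 and acnA, aconitate hydratase, had 88.4 ± 23.7 and 86.2 ± 31.7 FPKM (SD, n = 3), with a camera adjusted p of 0.539. Its largest change was that of a gene outside the theme, leuB (3-isopropylmalate dehydrogenase, log2 change -1.06, chosen after its value was seen).

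Synthesis, transport and sporulation lists did not pass either. Without oil replicate 1 their medians became 0.12 for fatty acid, 0.16 for peptidoglycan and 0.12 for amino acid synthesis, and 0.30 for sporulation. Those of purine and pyrimidine synthesis, multidrug efflux and iron became -0.03, 0.13 and -0.07. The medians below are those with all libraries. The median was -0.01 for fatty acid synthesis, where accC had 160 ± 43.4 and 169 ± 63.5 FPKM (SD, n = 3), and -0.08 for peptidoglycan synthesis, where a peptidoglycan glycosyltransferase had 75.8 ± 25.3 and 58.6 ± 22.4 FPKM (SD, n = 3). Both had a camera adjusted p of 0.741. The median was -0.15 for purine and pyrimidine synthesis, where guaA had 98.7 ± 9.62 and 120 ± 47 FPKM (SD, n = 3), and -0.08 for amino acid synthesis, where glnA, glutamine synthetase, had 101 ± 38.1 and 101 ± 38.5 FPKM (SD, n = 3). Their camera adjusted p were 0.735 and 0.481. Multidrug efflux had a median of 0.16, and a multidrug ABC transporter subunit (FOC77_RS25445) had 9.79 ± 2.5 and 22.9 ± 14.9 FPKM (SD, n = 3). Its camera adjusted p was 0.735, and exporters of metals and fluoride were among its members. Sporulation and spore genes had a median of 0.14 over 46 genes (camera adjusted p = 0.914), and spoVT had 286 ± 166 and 340 ± 139 FPKM (SD, n = 3). Over 6 genes of iron and siderophores the median was -0.27, with a camera adjusted p of 0.467, and an iron ABC transporter permease had 4.74 ± 2.55 and 4.89 ± 0.878 FPKM (SD, n = 3).

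**Figure D3:**
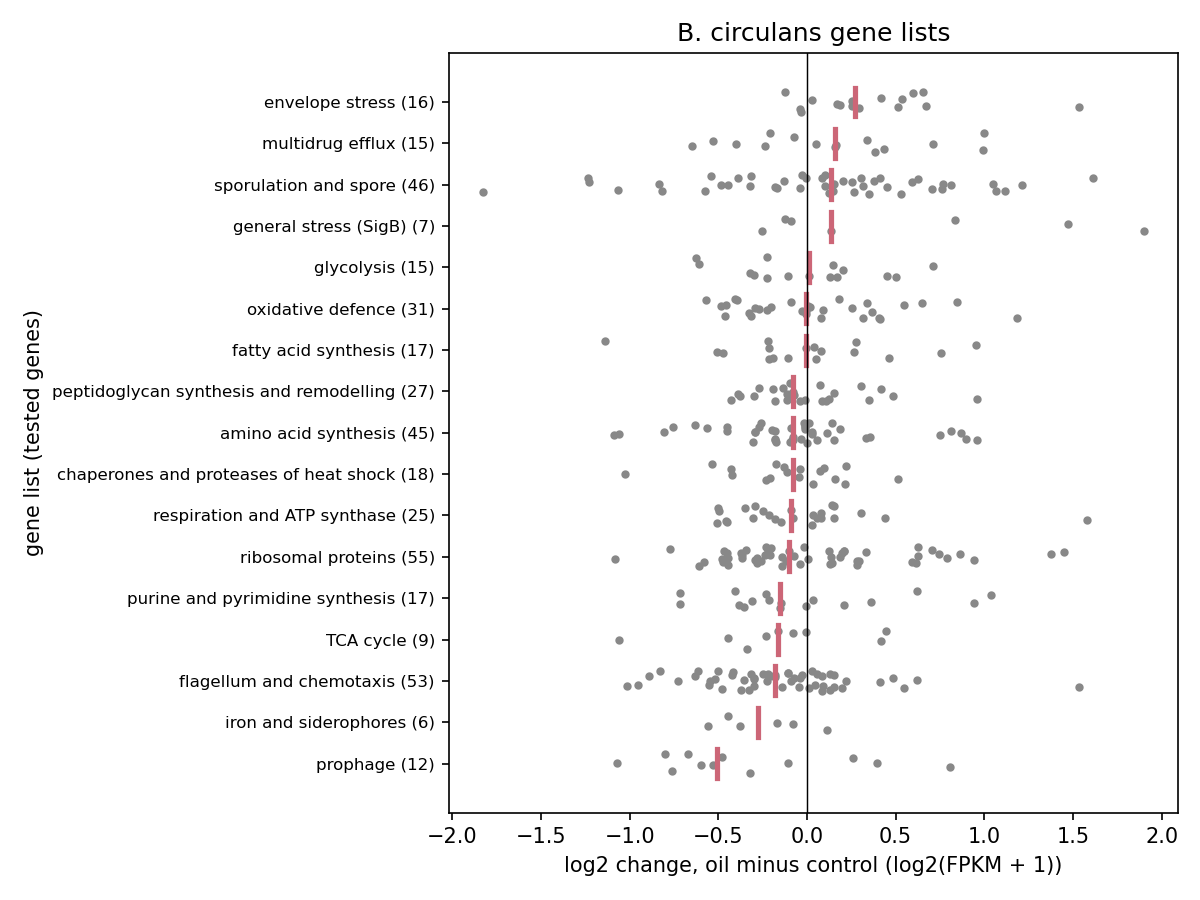
Log2 change of each tested gene of the 17 B. circulans gene lists (gray points, oil minus control on the log2(FPKM + 1) scale), with each list's median as a red bar and the number of tested genes in parentheses. Medians ran from -0.51 for prophage to 0.27 for envelope stress, and no list passed the threshold.

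The B. circulans libraries also differed in how much of the signal lay outside protein-coding genes. Protein-coding genes held between 9.55% and 23.8% of the reads of a library. ffs, the RNA of the signal recognition particle, chosen after its values were seen, had 105654 ± 41368 FPKM in controls and 226246 ± 139985 after the oil (SD, n = 3, exact permutation p = 0.3), with its highest value, 370275 FPKM, in oil replicate 1. Without oil replicate 1 the median log2 change over all tested genes was 0.21. It was 0.19 without control replicate 2 and -0.16 without oil replicate 3, so the dependence was not on 1 library alone. Without oil replicate 1 the median of prophage became -0.15 and that of envelope stress 0.57 (camera adjusted p = 0.173 for both). That of flagellum and chemotaxis became 0.11 (camera adjusted p = 0.718). In 5 simulations with the depth of these libraries the test recovered 6.4% of 2-fold and 60.2% of 4-fold changes, so changes of 2-fold were mostly not detectable at this depth and spread.

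In C. glabrata 2257 of 5155 tested genes were higher and 1564 were lower after the oil (limma, adjusted p under 0.05), 74.1% of the genes tested. Of these, 766 were higher and 489 lower by at least 2-fold, and 47 were higher and 21 lower by at least 8-fold. The table does not pair its tags with gene names. The largest rises were those of gene-CAGL0G03927g, from 13.9 ± 1.93 to 2391 ± 520 TPM (SD, n = 3, log2 change 7.30 with a standard error of 0.15, limma adjusted p = 4.24e-11), and gene-CAGL0I10010g, from 15.1 ± 2.26 to 2048 ± 525 TPM (SD, n = 3, limma adjusted p = 8.25e-11). The largest falls were those of gene-CAGL0D00418g, from 1504 ± 95.9 to 53 ± 1.53 TPM (SD, n = 3, log2 change -4.80 with a standard error of 0.08, limma adjusted p = 1.39e-11), and gene-CAGL0H06633g, from 857 ± 66.8 to 30.5 ± 3.4 TPM (SD, n = 3, limma adjusted p = 4.24e-11). All 4 kept their direction and call with median centring.

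The direction of the C. glabrata calls differed with expression level. Among the 1289 tested genes with the lowest means 809 were higher and 127 lower, with a median log2 change of 0.51, and among the 1289 with the highest means 418 were higher and 656 lower, with a median of -0.24. The most abundant gene held 4.38% ± 0.244 of the TPM of locus tags in controls and 12% ± 2.3 after the oil (SD, n = 3, exact permutation p = 0.1). Groups did not overlap for 77.3% of the tested genes, where each gene alone has a 10% chance. Genes share the same libraries, so a shift of whole libraries can separate many of them at once. The median gene was higher by 0.14 on the log2 scale. Median centring, which removes that shift, gave 1971 higher and 1959 lower genes, and quantile normalization 1805 higher and 1932 lower. Both settings even out the libraries by construction, so they do not test whether the excess of higher genes holds.

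In A. flavus 967 of 8472 tested genes were higher and 6043 were lower after the oil (limma, adjusted p under 0.05), and the median gene fell by 1.5 on the log2 scale. The size of that fall depended on the processing: the median log2 change was -1.86 with pseudocount 0.1, -0.95 with pseudocount 5, -1.03 without a filter and -1.83 with limma-voom. Relative to that shift, by median centring, 2620 genes were higher and 2370 were lower, and 661 genes were lower as deposited but higher after centring. Quantile normalization gave 2105 higher and 2709 lower. Centring moved every change up by the same amount. Genes above 0 thus stayed above it, and genes below 0 after centring had been below it before. Both scalings shared 967 higher and 2370 lower genes, and 208 and 64 by at least 8-fold. These overlaps follow largely from the shift and do not check 1 scaling by the other. The table does not pair its tags with gene names. The largest rises were those of gene-G4B84_008741, from 0.782 ± 0.674 to 2976 ± 234 TPM (SD, n = 3, log2 change 10.77 with a standard error of 0.24, limma adjusted p = 1.41e-08), and gene-G4B84_005952, from 1.41 ± 0.397 to 2222 ± 62.6 TPM (SD, n = 3, limma adjusted p = 2.05e-09). The largest falls were those of gene-G4B84_004704, from 190 ± 47.4 to 0.746 ± 0.676 TPM (SD, n = 3, log2 change -6.83 with a standard error of 0.35, limma adjusted p = 1.15e-06), and gene-G4B84_006057, from 153 ± 34.5 to 0.527 ± 0.913 TPM (SD, n = 3, limma adjusted p = 2.56e-06). The last had 251 reads on average in controls and 0.667 after the oil.

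Fewer A. flavus genes were detected after the oil. Locus tags at 0 numbered 1942 ± 257 in controls and 3852 ± 320 after the oil (SD, n = 3, exact permutation p = 0.1). With every library thinned to 3024380 reads in locus tags they numbered 2368 ± 165 and 3907 ± 272 (SD, n = 3). The median TPM of locus tags was 9.89 ± 0.286 in controls and 2.18 ± 0.176 after the oil, and the 100 most abundant tags of a library held 41.4% ± 0.512 and 55% ± 0.5 of the TPM of locus tags (SD, n = 3, exact permutation p = 0.1 for both). By expression, the median log2 change was -2.16 among 2118 tested genes with mean TPM from 5.72 to 18.5 and -0.71 among the 2118 with the highest means. Groups did not overlap for 84% of the tested genes, where each gene alone has a 10% chance. In B. circulans the share was 7.24%. A shift of whole libraries, such as the fall of the median gene, can separate many genes at once.

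**Figure D4:**
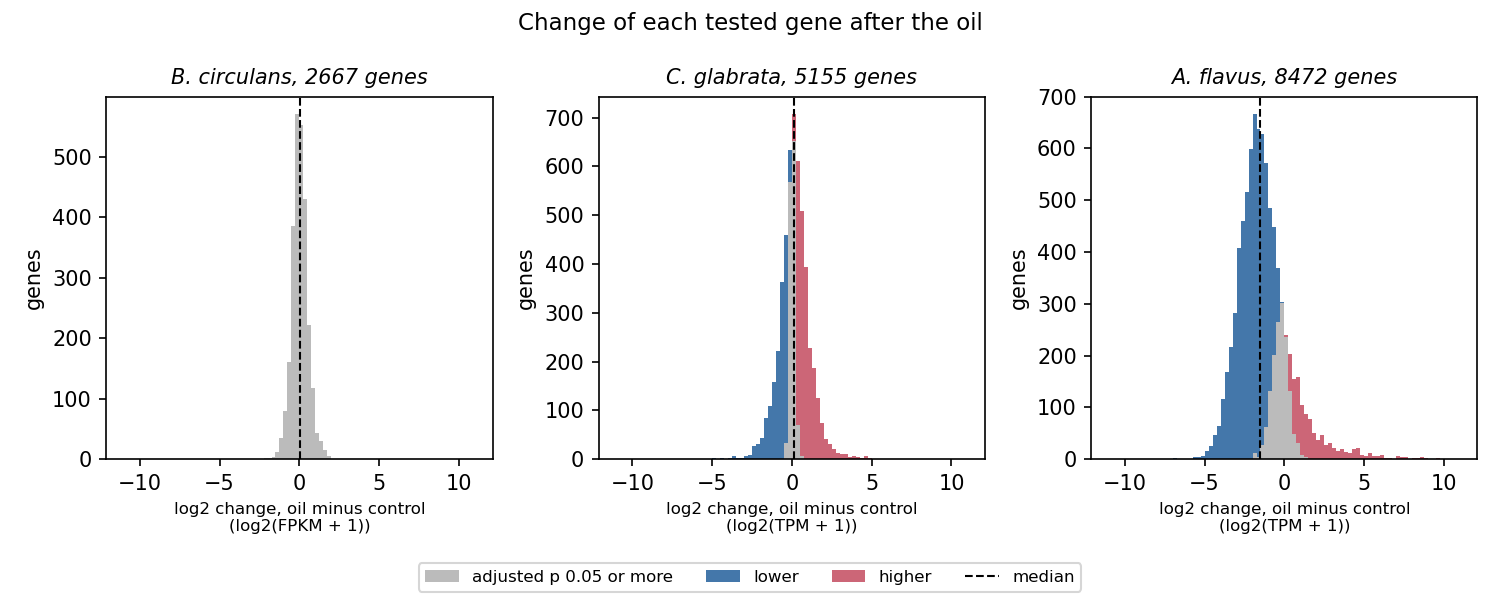
Log2 change of every tested gene after the oil in the 3 species, in genes per bin of log2 change, with genes past the threshold colored by direction, those not past it in gray and the median as a dashed line. No B. circulans gene passed, C. glabrata had 2257 higher and 1564 lower genes around a median of 0.14, and A. flavus had 967 higher and 6043 lower genes around a median of -1.5. With median centring the split was 1 and 2, 1971 and 1959, and 2620 and 2370.

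The 3 tables hold different genes and were normalized separately, in FPKM for B. circulans and in TPM for the fungi, so their genes and lists were not tested against each other.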

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

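The thinning, rescaling and spread comparisons in this part were set out before their results were seen, except that 2 settings were added after the values without them were seen: median centring in the comparisons of spread and of response size, and pseudocount 5 in those of the A. flavus median. At pseudocount 5 that median does not reach the bound of -1 set beforehand, so the bound can be applied only at the main pseudocount. The flagged differences between the fungi were not tested against each other, since their tables hold different genes.

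Detection moved in opposite ways in the fungi, in every library. Locus tags at 0 changed by -9.33 on average in C. glabrata after the oil and by 1909 in A. flavus. With the libraries of a species thinned to equal recovered reads in locus tags, they averaged 31.6 in controls and 15.5 after the oil in C. glabrata. In A. flavus they averaged 2368 and 3907. The recovered reads of C. glabrata leave out its most abundant gene. The median TPM of locus tags changed by 3.65 in C. glabrata and by -7.70 in A. flavus. The percentage of TPM in unnamed assembled features changed by -0.0842 points in C. glabrata and by 0.823 points in A. flavus. These unnamed features, which the main tests leave out, held changes in both directions: of 55 tested in C. glabrata 32 were higher and 7 lower after the oil, and of 845 in A. flavus 193 were higher and 285 lower (limma, adjusted with all genes). In B. circulans 0 of 207 passed by limma, with 12 at an unadjusted p under 0.05.

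In A. flavus the median gene fell by 1.5 on the log2 scale, and by 0.95 with pseudocount 5. With the 100 genes of the highest mean left out and the rest rescaled, the median was still -1.35 (-0.92 with pseudocount 5), which argues against those genes as the whole cause. With control reads thinned to the mean oil depth it was -1.49 (-0.95 with pseudocount 5). Thinning keeps the expected value of each gene, so it could hardly move the median. It argues only against the sampling of fewer reads as the whole cause. A rise spread over more than 100 abundant genes, a difference in RNA quality and a response to the oil stay open, and TPM cannot show a change in RNA per cell. Only 1 of the 10 splits of the 6 libraries, the real one, called as many genes (7010, against 0 in the highest other), but 10 splits are too few for a share under 0.05.

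In B. circulans no gene passed while 3821 passed in C. glabrata. C. glabrata thinned to the reads per gene of B. circulans, and put on its scale, still had 1875 calls on average over 10 draws, which argues against depth per gene as the whole cause. The median residual SD of B. circulans was 2.25 times that of the thinned C. glabrata, and 1.7 times after median centring. The SD of log2 changes beyond the replicate spread was 0 in B. circulans and 0.817 in thinned C. glabrata without centring. That 0 is a floor, set where the changes vary no more than their standard errors, and does not measure an absent response. With centring the SDs were 0.276 and 0.818, a ratio of 0.338. A larger spread between libraries and a smaller response may therefore both contribute. With the species as the only contrast they cannot be weighed against culture or library differences. The real count is 0, which all 10 splits of the B. circulans libraries must reach (2 in the highest other), so they show nothing about chance.

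In C. glabrata 1 of the 10 splits, the real one, gave 3821 calls, against 0 in the highest other, and 10 splits are too few for a share under 0.05.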

How the results depend on the processing

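Chosen after seeing the data were limma-voom on recovered reads, unnamed features included, the replicate block with median centring, and the scaling of B. circulans to protein-coding reads. The planned count test, the fungal gene lists and the lists side by side across species were not run. No named gene and no list changed direction with a call under any alternative, and the causes of the changes below were not tested except where fewer genes or libraries entered.

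In B. circulans, genes higher and lower numbered 1 and 2 with a mean of at least 10 (fewer genes tested), 1 and 2 with median centring, and 1 and 4 with quantile normalization. With robust priors, with unnamed features included and with the scaling to protein-coding reads 1 gene was higher and 0 lower. Leaving out a library gave 0 to 3 higher and 0 to 1 lower: 3 and 0 without control replicate 2, 1 and 1 without control replicate 3, and 3 and 1 without oil replicate 2. The called genes were FOC77_RS25265, FOC77_RS23665, FOC77_RS00830 and celB, and, chosen after their values were seen, dnaJ, rapZ, a protein arginine kinase, a YezD family protein and 4 hypothetical proteins. Of the lists, 2 passed with pseudocount 0.1 (prophage, and flagellum and chemotaxis), 1 with a mean of at least 10 (prophage), 3 with median centring and 3 with block and centring (those 2 and envelope stress), 2 with the scaling to protein-coding reads (prophage and envelope stress), and 0 to 1 with a library left out: prophage without control replicate 3, flagellum and chemotaxis without oil replicate 3. With an estimated correlation or fry 0 passed.

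In C. glabrata a 2-fold minimum gave 766 higher and 489 lower, and the other alternatives stayed within 1.5 times. In A. flavus a mean of at least 10 gave 3921 lower, median centring 2620 higher and 2370 lower, quantile normalization 2105 and 2709, and block with centring 2597 and 2258. Leaving out a library gave 2091 to 2434 higher and 1427 to 1632 lower in C. glabrata, and 883 to 963 and 5651 to 6103 in A. flavus. limma-voom, which kept the deposited scaling, gave 2266 and 1563 in C. glabrata and 970 and 6076 in A. flavus.

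The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered libraries correlated between -0.06 and 0.09 across genes, and not every library correlated best with its own number. These values show no shared effect of the number, but with 3 libraries per group they cannot settle whether samples were paired. The replicate block gave 1 higher gene (FOC77_RS25265), 0 lower genes and 0 lists in B. circulans, where the block with median centring gave 0 and 0 genes. The block alone gave 2267 and 1562 genes in C. glabrata, and 956 and 6053 in A. flavus. In B. circulans the median tested gene had 14 to 30 reads in a library, which limits the precision of its values.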

Other observations

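The test of sugar uptake was chosen after its genes were seen, and the test of neighbouring tags against shuffled tags before. The comparison with pairs of libraries of 1 group was added after a first value was seen, and the runs of tags were not among the bounds set beforehand. Sugar uptake stood out in B. circulans without having been a list. Among 42 tested genes of PTS and sugar transport and extracellular solute binding, 31 were above 0, with a median log2 change of 0.29. A hypothesis is that these genes rise together after the oil. With the 3 named genes left out, 28 of 39 genes were above 0 with a median of 0.26, and camera gave p = 0.00715 at the preset correlation but p = 0.329 with an estimated one. The median over all tested genes was 0.04 with all libraries. Without oil replicate 1 the camera p at the preset correlation was 0.593. The median of the 39 genes was then 0.15, below the 0.21 over all tested genes. The data thus leave it open whether the sugar uptake genes may rise as a group.

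Genes with consecutive locus tags changed alike. Across neighbouring pairs the log2 changes correlated at 0.26 in A. flavus (7210 pairs), 0.19 in C. glabrata (5097 pairs) and 0.16 in B. circulans (1864 pairs). Shuffling changes within 10 classes of mean expression gave at most 0.0651, 0.0597 and 0.0718 in 1000 shuffles, and differences between 2 libraries of 1 group gave at most 0.0713, 0.122 and 0.0932. In A. flavus 9 runs of at least 4 consecutive tags moved by at least 4-fold one way relative to the median gene, the longest of 8 tags, against a median of 1 run and a maximum of 6 in the shuffles. C. glabrata and B. circulans had 0 such runs, and their longest stretches, of 3 tags and 1 tag, did not exceed the shuffled maxima of 4 and 1. The correlations are consistent with neighbouring genes responding together, as a hypothesis across genes, which are not independent replicates. Reads shared by overlapping neighbours were not tested. In B. circulans no gene passed the threshold, so its correlation alone does not show a response to the oil.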
